A study of Drosophila melanogaster with 27 samples.

How the data were processed

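The counts of reads per gene were made by the authors and are used as deposited: per the submitters' processing notes, reads were aligned with TopHat2 to dm3 and counted with HTSeq. The versions of these tools, the annotation release, the counting mode and the strand setting are not given in the sources used here. Per the labels' protocols, discs of 35 to 50 wandering last-instar larvae, raised at 25 °C, were dissected for each library, replicates are independent dissections, and RNA was extracted with a column kit. The tables hold 15348 genes and 5 summary lines of HTSeq for each of 27 libraries in 15 groups of genotype and disc. Of the gene identifiers 14639 had a symbol in the reference, and 1528 genes had no read in any library. The genotype label of the eye-antennal libraries titled sd names the kay hairpin. The title was followed, and other readings were run as alternatives. The 8 libraries of CG6272, Stat92E and kay have a second form of file name, which coincides with genotype, so that a difference between sequencing runs could not be separated from these genotypes. Each was also compared with the others of that form.

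Reads assigned to genes averaged 14.2 M in control, 12.8 M in tumour, 13.1 M in sd, 14.8 M in CG6272, 13.4 M in tai and 14 M in Stat92E libraries, and 14.4 M in the kay library. The summary lines for reads aligned to several places made up 17.6% of all lines in control and 67.1% in tumour libraries on average, 29% in CG6272, 49.9% in Stat92E, 51.4% in tai, 55.1% in sd and 61.5% in the kay library, and lines without a gene 3.14% in control and 1.56% in tumour libraries. Summary lines were left out of the library sizes. Replicate pairs correlated at 0.936 to 0.983 in log CPM, and none was identical. The first components of the log CPM held 25.6%, 19.8% and 10.7% of the variance.

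Genes with at least 1 CPM in at least 2 libraries were tested, which left 9814. Libraries were scaled by TMM, and a model with 1 mean for each group was fitted to all libraries with 12 residual degrees of freedom. Each comparison was tested with edgeR's quasi-likelihood F-test with robust dispersion (common biological coefficient of variation 0.283, median prior degrees of freedom 2.76), with the Benjamini-Hochberg adjustment over the tested genes at a threshold of 0.05. Tumour was compared with control as the mean over discs and in each disc, the difference of that effect among discs was tested jointly, and hairpin genotypes were compared with tumours of the same discs, averaged over discs. A group with 1 library was assumed to vary like the others. Log2 fold changes are given with SE, CPM values with SD. The SE is the absolute log2 fold change divided by the square root of F.

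Gene lists were written before the data were examined, as were the comparisons, the tests and most of the other settings. The 29 lists held 370 members, of which 341 were matched (328 distinct genes). Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals, each adjusted over the lists of a comparison. Named genes are the targets in every comparison, members of the lists, and those with the largest changes: 10 rises and 10 falls for tumour against control and 5 and 5 for each hairpin, among genes past the threshold with a mean of at least 10 CPM in the higher genotype and every library on the same side in every disc. Which list members to give as examples was chosen after the values were seen, and most examples whose call ended without 1 library were then left out of the text. They still count in the lists. Reversal was tested with camera on genes changed at least 2-fold in wing discs, and again with separate tumour dissections for the wing genes and the hairpins, a test added after the data were seen. Sharing among hairpins was compared with 20 simulations in which only the tumour libraries were shared.

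Counts of the same groups were simulated with 50 genes changed at each of 1.5-, 2-, 4- and 8-fold. Recovery was 52%, 70%, 86% and 90% for tumours (3.2% false calls) and 20%, 42%, 66% and 80% for wing discs (4.6%). It was 40%, 64%, 68% and 94% for sd (0.7%) and 50%, 56%, 80% and 84% for tai (4.3%). For kay it was 16%, 44%, 64% and 88% (4.5%). Dissection correlation was not simulated, so real rates can differ.

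Alternatives were DESeq2 size factors, no count filter, a minimum of 5 CPM, DESeq2's test, limma-voom with the dissection, taken as genotype and replicate number, as a random block (correlation 0.442; the day labels of the sd libraries cross these numbers), the replicate number as a block, additive terms, the compared libraries alone, each library left out, other readings of the sd titles, and comparison with other knockdowns. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Reads, splicing, sequence variants and transgene sequences were not analysed here.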

Results

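Gene expression was measured by RNA sequencing in imaginal discs, the larval epithelial sacs that form the adult eyes, antennae, legs and wings of Drosophila melanogaster. The hh-Gal4 driver is active in the posterior compartment of each disc. In control discs it drove GFP with a hairpin against luciferase, and in tumour discs it drove a hairpin against the polarity gene scrib, an activated Ras transgene and the luciferase hairpin. Further genotypes replaced the luciferase hairpin of the tumour with a hairpin against sd, CG6272, tai, Stat92E or kay, which encode transcription factors or a coactivator (tai). Control and tumour had 2 libraries in each of eye-antennal, leg and wing discs. The sd and CG6272 genotypes had 2 libraries in each of eye-antennal and leg discs, tai had 2 eye-antennal and 1 leg library, Stat92E had 1 eye-antennal and 2 leg libraries, and kay had 1 eye-antennal library. Each library held 11.7 to 16 M reads assigned to genes. A log2 change is followed by its SE, and a mean in CPM (counts scaled to library size) by its SD.

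The genes that the transgenes target or carry were read first in every library. Ras85D (FBgn0003205), the gene of the activated Ras transgene, averaged 894 ± 295 CPM (n = 6) in tumour and 287 ± 18.5 CPM (n = 6) in control libraries, with ranges of 585 to 1310 and 265 to 314. Reads of the transgene and of the resident gene were counted together. The hairpin target scrib (FBgn0263289) averaged 245 ± 18.2 CPM in tumour and 368 ± 40.6 CPM in control libraries, a log2 change of -0.58 ± 0.07 (adjusted p = 9.95e-06). CG6272, listed under its symbol Irbp18 (FBgn0036126), fell from 65.4 ± 19 CPM (n = 4) in eye-antennal and leg tumours to 10.8 ± 1.53 CPM (n = 4) under its own hairpin (-2.60 ± 0.23, adjusted p = 4.32e-06). Stat92E (FBgn0016917) fell from 223 ± 8.15 CPM to 173 ± 8.09 CPM (n = 3) under its hairpin (-0.39 ± 0.07, adjusted p = 0.0032).

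The other hairpins did not lower their target past the test's threshold, so their samples are called libraries titled sd, tai and kay. The target sd (FBgn0003345) averaged 249 ± 52.6 CPM (n = 4) in libraries titled sd and 268 ± 14.9 CPM in tumours (-0.11 ± 0.12, adjusted p = 0.565). Without replicate 1 of the eye-antennal or of the leg discs titled sd the sign turned (0.03 ± 0.12 and 0.05 ± 0.11). Their sd levels differed by replicate number: sd stood at 205 and 202 CPM in replicate 1 of eye-antennal and leg discs and at 288 and 300 CPM in replicate 2, against 248 to 283 CPM in the tumours. The target tai (FBgn0041092) averaged 156 ± 4.05 CPM (n = 3) in libraries titled tai and 187 ± 20.6 CPM in tumours (-0.25 ± 0.13, adjusted p = 0.348). The target kay (FBgn0001297), which encodes the Fos subunit of AP-1, stood at 131 CPM in the single library titled kay and at 338 ± 135 CPM (n = 2) in eye-antennal tumours (-1.37 ± 0.45, adjusted p = 0.221). The eye-antennal libraries titled sd carry a genotype label that names the kay hairpin. In them kay stood at 185 and 171 CPM, and in the leg libraries titled sd at 207 and 199 CPM, where tumours had 242 to 586 CPM.

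**Figure D1:**
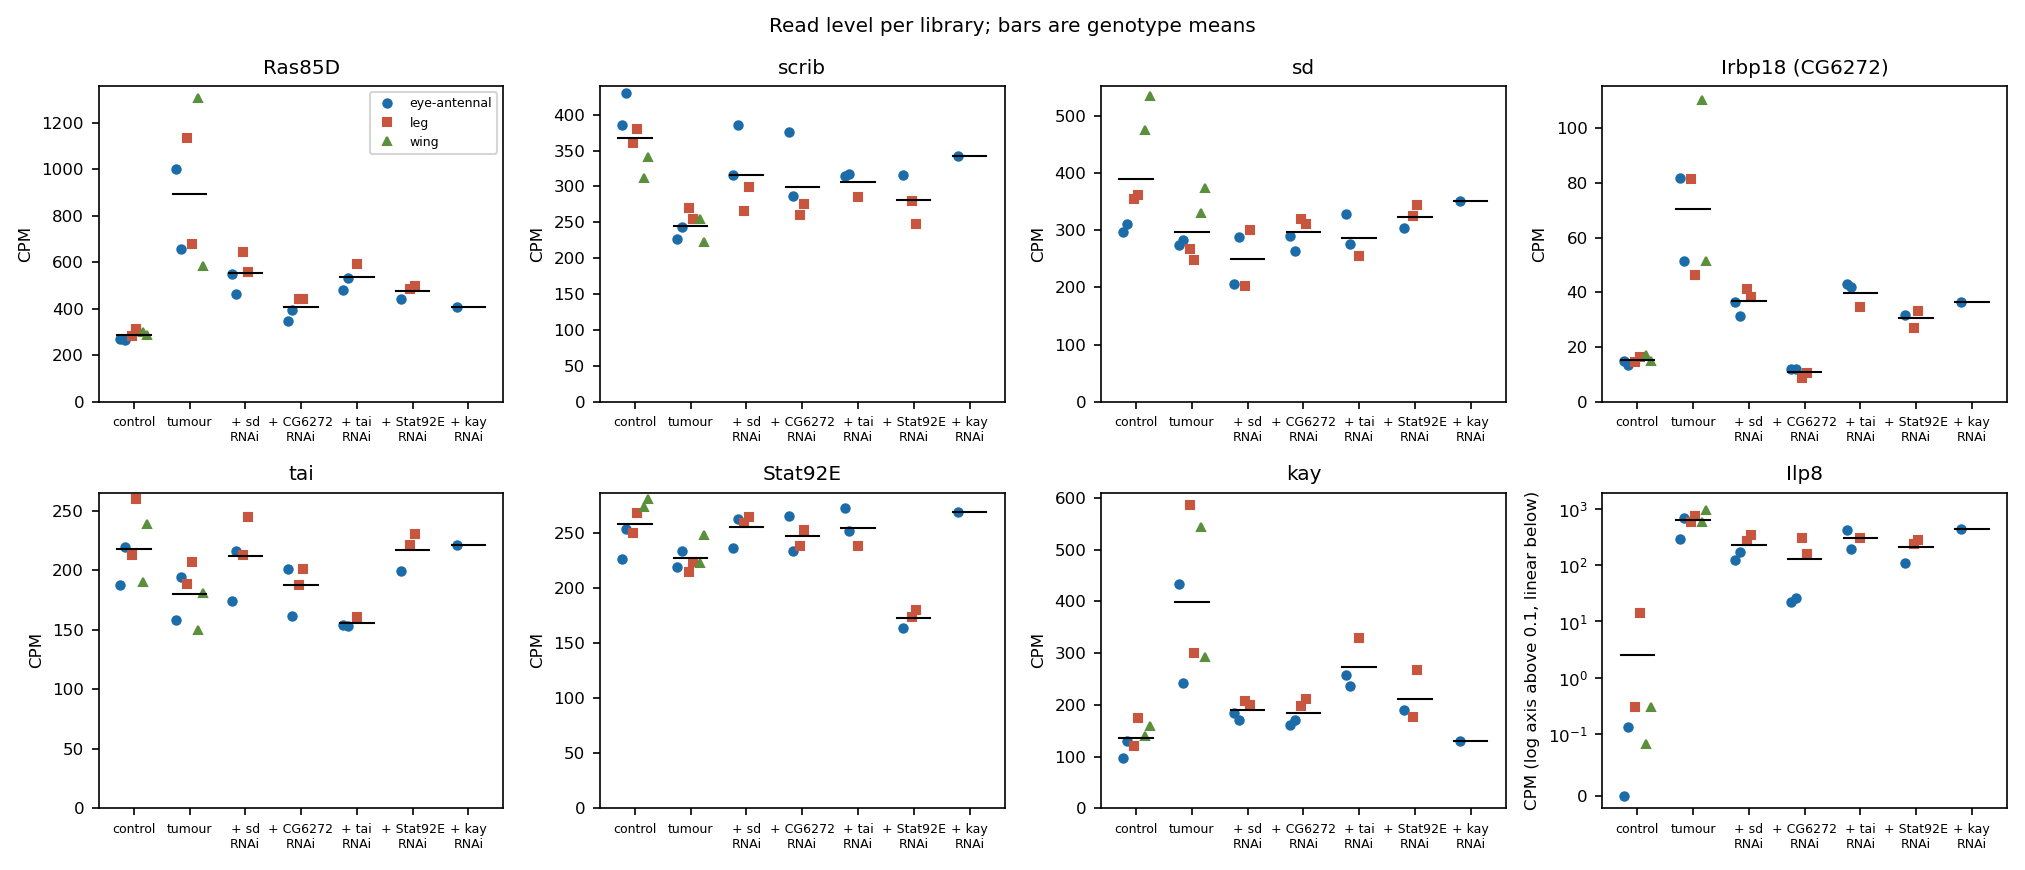
Read level in CPM of the 7 genes that the transgenes target or carry, and of Ilp8, in each library, by genotype (points, coloured by disc; bars are genotype means). Irbp18 stands at 8.7 to 12 CPM under the CG6272 hairpin, and the sd levels of the libraries titled sd overlap those of the tumours.

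The tumour libraries were set against the control libraries to ask which genes change with scrib knockdown and activated Ras in all 3 discs. Tumour discs expressed Ilp8, a relaxin-like peptide of damaged or overgrown discs that delays pupariation, at 650 ± 220 CPM against 2.5 ± 5.74 CPM in control discs (log2 change 10.34 ± 0.74, adjusted p = 6.01e-08, n = 6 and 6). The control mean was 0.161 CPM without replicate 2 of the leg discs. At camera's preset correlation the lists of JNK targets, JAK/STAT genes, EGFR outputs and bZIP stress genes stood above the other genes, and those of Notch targets, ecdysone pathway genes, eye genes and wing disc genes below them. With an estimated correlation none of these 8 lists passed (adjusted p = 0.425 for each). Of 9814 genes tested, 5180 changed on average over the discs, 2777 upward and 2403 downward, and 1058 and 497 of these by at least 2-fold. The tests treat libraries as independent. Discs of 1 genotype with the same replicate number had correlated deviations (median 0.26), and with the dissection as a block limma-voom gave 3605 genes, against 4882 without. Control larvae were dissected on day 5 and tumour larvae on day 9 (replicate 1) or day 11 (replicate 2), so the genotypes also differ in the age of the larvae.

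The genes with the largest rises included the cytochrome P450 gene Cyp6a17 (99.7 ± 40.9 against 0.263 ± 0.569 CPM) and the glutathione transferase gene GstD5 (41.1 ± 30.9 against 0.367 ± 0.657 CPM). Others were the cuticle gene Cpr64Ac (69.6 ± 78.3 against 0.0584 ± 0.0795 CPM) and Osi14, of the Osiris family of cuticle-forming cells (61.8 ± 55.2 against 1.86 ± 2.09 CPM). The remaining members of that set were CG14695 (54.2 ± 7.42 against 0.289 ± 0.334 CPM) and CG32241 (91.1 ± 52.8 against 1.23 ± 2.75 CPM), with CG1494 (22.4 ± 6.89 against 0.221 ± 0.215 CPM), CG12607 (21 ± 14.8 against 0.102 ± 0.249 CPM) and CG5646 (20.4 ± 18.7 against 0.222 ± 0.182 CPM). Without replicate 2 of the control leg discs the control means were 0.104 CPM for CG32241, 0.0318 for Cyp6a17, 0.102 for GstD5, 0.0294 for Cpr64Ac, 0.17 for CG14695, 0.143 for CG1494 and 0 for CG12607. Among the largest falls were 4 genes of the mitochondrial genome: mt:CoIII (0.409 ± 0.245 against 183 ± 27 CPM), mt:ND4 (0.0918 ± 0.119 against 68.7 ± 6.52 CPM), mt:ND1 (0.203 ± 0.187 against 61.6 ± 15.8 CPM) and mt:ND5 (0.0267 ± 0.0417 against 25.3 ± 6.27 CPM). Without wing replicate 2 tumours had 0.0524 CPM of mt:ND4 and 0.0176 of mt:ND5, and without leg replicate 1 0.0144 of mt:ND5. Reepl1 had the same pattern (0.0844 ± 0.096 against 38.5 ± 2.08 CPM). All hairpin genotypes shared the tumour's low level of mt:CoIII, with group means of 0.215 to 1.68 CPM. The other members were the ecdysone-response genes Hr3 (-5.74 ± 0.72), ImpE2 (-5.50 ± 0.55) and Blimp-1 (-4.93 ± 0.66), the fat body gene Fbp1 (-5.52 ± 1.14), and CG15905 (-5.21 ± 0.32).

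Targets of JNK signalling, which tissue damage and loss of polarity activate, had the highest median of the 29 lists: 12 of 13 rose and 1 fell (median 2.04, camera adjusted p = 1.41e-06, and 0.425 with an estimated correlation). List counts adjusted over the list alone were the same unless given. Mmp1, a matrix metalloprotease, rose by 2.81 ± 0.23 from 110 ± 35.7 to 787 ± 227 CPM. The ETS factor Ets21C went from 2.42 ± 1.33 to 128 ± 35.6 CPM. The JNK phosphatase gene puc rose by 1.80 ± 0.15 and kay by 1.55 ± 0.20. By contrast egr, the ligand that activates JNK, fell by 0.47 ± 0.13. Of 12 JAK/STAT genes, 7 rose and 2 fell (median 1.53, camera adjusted p = 0.0124, and 0.425 with an estimated correlation). The cytokine gene upd1 went from 6.48 ± 2.51 to 77.8 ± 20 CPM, upd2 from 1.52 ± 1.85 to 51.7 ± 21.2 CPM and upd3 from 1.19 ± 0.783 to 53.5 ± 27.4 CPM. The feedback gene Socs36E rose by 2.47 ± 0.11 and chinmo by 4.10 ± 0.23, while the kinase gene hop and Stat92E fell by 0.21 ± 0.06 and 0.19 ± 0.05. EGFR and Ras outputs rose in 9 of 11 cases and none fell (median 1.06, camera adjusted p = 0.00123, and 0.425 with an estimated correlation). They included the antagonists sty (1.97 ± 0.14) and aos (1.61 ± 0.18), the effector pnt (1.36 ± 0.10) and ImpL2 (3.55 ± 0.29), which encodes an insulin antagonist.

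Of 11 genes of the bZIP stress response, 10 rose and 1 fell (median 1.38, camera adjusted p = 0.0014, and 0.425 with an estimated correlation): Irbp18, the C/EBP-type factor named CG6272 in the labels, rose by 2.21 ± 0.19. Gadd45 rose by 2.78 ± 0.18, Xrp1 by 1.30 ± 0.12 and the translation repressor Thor by 2.80 ± 0.54, while aay fell by 2.65 ± 0.21. Basement membrane and matrix genes rose in 9 of 13 cases and none fell (10 rose adjusted over the list alone, median 0.92, camera adjusted p = 0.0343, and 0.555 with an estimated correlation). Among them were Timp at 1.39 ± 0.20 and the collagen gene vkg at 1.05 ± 0.28. Heat shock and antioxidant genes rose in 6 and fell in 3 of 14 cases (median 0.82, camera adjusted p = 0.39). The gene GstD1 rose by 1.97 ± 0.19, and Cat, the catalase gene, fell by 1.76 ± 0.08 and Hsp27 by 1.64 ± 0.38. Glycolytic genes rose in 7 of 11 cases and none fell (median 0.73, camera adjusted p = 0.105). Ldh, which regenerates NAD for glycolysis, had the widest change of them (5.87 ± 0.86). Also higher were Ald1 at 1.18 ± 0.32 (0.77 ± 0.27 without replicate 1 of the eye-antennal tumours) and Hex-A at 1.01 ± 0.25. Immune genes rose in 7 and fell in 1 of 20 cases (6 rose adjusted over the list alone, median 1.42, camera adjusted p = 0.154): the recognition gene PGRP-SA rose by 3.54 ± 0.26 and the receptor gene Tl fell by 1.16 ± 0.18. Apoptosis genes moved both ways, with 3 of 11 higher and 4 lower (median 0.07, camera adjusted p = 0.785). The gene Corp rose by 3.64 ± 0.22, the proapoptotic gene rpr by 0.98 ± 0.11 and the caspase gene Dronc by 0.70 ± 0.09. The caspase inhibitor gene Diap1 fell by 0.48 ± 0.12.

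Targets of Yorkie and Sd, the Hippo pathway's effectors, rose in 8 and fell in 2 of 14 cases (9 and 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.108). The gene dally rose by 1.07 ± 0.09, fj by 0.93 ± 0.10, kibra by 0.85 ± 0.11 and ex by 0.39 ± 0.09. Diap1 and CycE fell by 0.48 ± 0.12 and 0.42 ± 0.07. Notch targets fell in 10 of 12 cases and none rose (median -0.69, camera adjusted p = 0.00123, and 0.425 with an estimated correlation), E(spl)m2-BFM by 1.63 ± 0.16 and E(spl)m7-HLH by 1.13 ± 0.11. Of 9 Hedgehog pathway and posterior genes, 2 rose and 4 fell (median -0.21, camera adjusted p = 0.154). The genes hh and inv, markers of the posterior cells in which the driver is active, rose by 0.42 ± 0.09 and 0.53 ± 0.11. The gene ci, expressed in anterior cells, fell by 1.25 ± 0.08. Wingless and Dpp genes rose in 1 and fell in 6 of 12 cases (median -0.49, camera adjusted p = 0.0343, and 0.54 with an estimated correlation): the Dpp repressor gene brk rose by 1.06 ± 0.10. The genes bi, Dad and Notum fell by 1.65 ± 0.09, 0.70 ± 0.06 and 0.66 ± 0.14. Polarity and junction genes rose in 4 and fell in 9 of 17 cases (median -0.15, camera adjusted p = 0.105). Among them were sdt at 0.69 ± 0.11, l(2)gl at 0.49 ± 0.08, arm at -0.39 ± 0.04, Fas3 at -0.58 ± 0.05 and scrib itself at -0.58 ± 0.07. Cell cycle and replication genes fell in 10 and rose in 1 of 20 cases (median -0.26, camera adjusted p = 0.00497, and 0.6 with an estimated correlation).

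Ecdysone pathway genes, which time the larval molts and pupariation, fell in 10 and rose in 3 of 17 cases (median -0.80, camera adjusted p = 0.0343, and 0.425 with an estimated correlation). Beside Hr3, ImpE2 and Blimp-1, the genes Eip75B (-1.40 ± 0.13), ImpE1 (-2.67 ± 0.26) and ImpE3 (-4.12 ± 0.36) fell, and the receptor gene EcR (0.76 ± 0.09) and ftz-f1 (2.97 ± 0.18) rose. Eye and retinal genes fell in 11 and rose in 1 of 19 cases (median -1.37, camera adjusted p = 0.00121, and 0.425 with an estimated correlation). Among them were sens at -2.91 ± 0.25, Optix at -2.45 ± 0.32, eya at -1.82 ± 0.21 and oc at 1.30 ± 0.18. Wing disc genes fell in 8 of 12 cases and none rose (9 fell adjusted over the list alone, median -0.82, camera adjusted p = 0.0014, and 0.425 with an estimated correlation), Doc2 by 2.27 ± 0.21 and vg by 1.09 ± 0.29. Leg disc genes fell in 8 and rose in 2 of 15 cases (9 fell adjusted over the list alone, median -0.33, camera adjusted p = 0.0814). The gene dac fell by 2.31 ± 0.22 and al by 1.5 ± 0.11, and Lim1 rose by 0.67 ± 0.11 and dysf by 3.65 ± 0.19.

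Markers of tissues that adhere to discs gave the background of the dissections. Fat body genes fell in 6 of 8 cases (median -3.53, camera adjusted p = 0.0543). Salivary glue genes fell in 6 of 6 (median -4.94, camera adjusted p = 0.0428, and 0.555 with an estimated correlation), Sgs3 among them (-7.32 ± 1.58). The summed fat body markers spanned 462 to 8500 CPM in control and 39.5 to 289 CPM in tumour libraries. Hemocyte genes rose in 3 of 10 cases (2 adjusted over the list alone, median 0.83, camera adjusted p = 0.39), Hml by 2.74 ± 0.53 and Sr-CI by 1.72 ± 0.43. Adepithelial myoblast genes fell in 4 of 6 cases (median -0.65, camera adjusted p = 0.0543). Larval muscle genes rose in 1 of 8, Mlc2 at 1.83 ± 0.50 (median 0.09, camera adjusted p = 0.986). Tracheal genes rose in 2 and fell in 1 of 5 cases (4 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.489). Neuronal genes rose in 1 and fell in 2 of 9 cases (1 and 1 adjusted over the list alone, median -0.39, camera adjusted p = 0.635). Glial genes rose in 2 and fell in 3 of 7 cases (median 0.07, mean -0.04, camera upward, adjusted p = 0.993). Of 5 prepupal cuticle genes Ccp84Aa fell (-2.09 ± 0.64; list median -0.59, camera adjusted p = 0.518). Ccp84Aa had -1.64 ± 0.84 with adjusted p = 0.124 without replicate 2 of the control wing discs, and -3.38 ± 0.80 without replicate 1 of the leg tumours. Of 5 germline genes AGO3 and piwi rose (1.92 ± 0.17 and 1.19 ± 0.27) and krimp fell (-1.97 ± 0.19, list median 0.04, camera adjusted p = 0.857).

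The discs were compared to ask where the tumour's effect depends on the tissue. Genes that pattern single discs moved both ways: so, Dll, ato and Doc2 fell in some discs, and dysf rose (in leg discs from 53.1 to 198 CPM). The gene so, an eye selector, fell from 135 to 40.6 CPM in eye-antennal discs (-1.74 ± 0.29) and did not pass in leg or wing discs (adjusted p of the difference 0.0364). Dll, which makes distal limb, fell from 122 to 35 CPM in wing discs (-1.81 ± 0.30) and did not pass in eye-antennal discs (adjusted p of the difference 0.0218). The proneural gene ato fell in eye-antennal discs from 46.8 to 11.2 CPM (-2.06 ± 0.31), and Doc2 in leg (-2.82 ± 0.37) and wing discs (-3.33 ± 0.37). Tested alone, eye-antennal discs gave 2868 genes (1676 higher, 1192 lower), leg discs 3760 (1937 and 1823) and wing discs 2980 (1597 and 1383). Without 1 library the count fell to 1787 or 1818 in eye-antennal discs (control replicates 1 and 2) and to 1786 or 1916 in wing discs (control replicate 2, tumour replicate 1). A test of the difference itself called 322 genes as disc-dependent, and 183, 186, 171 or 210 without replicate 1 or 2 of the control eye-antennal or replicate 1 or 2 of the control wing discs. Among them Scr, the Hox gene of the first thoracic segment and labium, rose in eye-antennal discs (13.2 to 48.6 CPM, 1.88 ± 0.65) and fell in leg discs (482 to 82.7 CPM, -2.54 ± 0.63; adjusted p of the difference 0.0363). Its rise in eye-antennal discs was 0.95 ± 0.71 with adjusted p = 0.377 without tumour replicate 1, and had adjusted p of 0.208 and 0.115 without control replicate 1 or 2. The distal leg gene al rose in eye-antennal discs (0.60 ± 0.19) and fell in leg (-2.39 ± 0.20) and wing discs (-2.72 ± 0.21; adjusted p of the difference 4.09e-05). The rise of al had adjusted p of 0.221, 0.0749 and 0.136 without control replicate 1, tumour replicate 1 or tumour replicate 2. The posterior genes hh and inv rose in eye-antennal discs (1.33 ± 0.16 and 1.47 ± 0.19) and not past the threshold in leg or wing discs (adjusted p of the difference 0.00335 and 0.00465). The lists with most disc-dependent members were leg disc genes (9 of 15) and eye and retinal genes (7 of 19), followed by Wingless and Dpp genes (4 of 12), Notch targets (3 of 12), Hedgehog pathway genes (3 of 9) and wing disc genes (3 of 12).

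The discs of each genotype were compared with each other. Differences among the 3 discs were called for 1161 genes in control and 808 genes in tumour larvae. The first count was 739, 762, 684 or 693 without replicate 1 or 2 of the control eye-antennal or of the control wing discs, and the second 472 or 503 without replicate 2 of the eye-antennal or of the leg tumours. Eye and retinal genes differed among discs in 16 of 19 cases in control and 15 in tumour larvae, wing disc genes in 10 and 8 of 12, and leg disc genes in 14 and 13 of 15. The eye gene eya, for example, stood at 79.3, 5.58 and 22.1 CPM in eye-antennal, leg and wing tumours, against 374, 24.7 and 46.2 CPM in the controls.

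Libraries titled sd (days 7 to 8) were set against eye-antennal and leg tumours (days 9 and 11) to ask which genes depend on sd. The growth factor gene Pvf1 fell by 2.86 ± 0.17 (adjusted p = 1.77e-07). Of 14 Yorkie targets 1 rose and fj (-1.26 ± 0.12), kibra (-0.95 ± 0.14) and dally (-0.53 ± 0.11) fell, against 7 that fell under CG6272 knockdown. The test called 2091 genes, 909 higher and 1182 lower, and 124 and 407 of these by at least 2-fold (n = 4 and 4). The count was 1254 or 1309 without replicate 1 of the eye-antennal or of the leg tumours and 1263 with only the libraries compared, and limma-voom gave 1822 without and 1132 with the dissection as a block. The largest rises were spok (17.1 ± 17.5 against 1.7 ± 2.22 CPM), which encodes an enzyme of ecdysone synthesis in the prothoracic gland, CG15905 (3.38 ± 0.37), Obp99a (2.74 ± 0.37), CG42749 (2.37 ± 0.25) and the ecdysone-response gene ImpE2 (2.15 ± 0.58). The largest falls were Cpr64Ac (0.114 ± 0.0993 against 62.9 ± 82.9 CPM), CG17350 (0.465 ± 0.603 against 84.6 ± 18.7 CPM), CG6933 (0.074 ± 0.103 against 139 ± 250 CPM), CG7715 (0.0566 ± 0.0738 against 48.7 ± 83.5 CPM) and CG15818. The latter had 0 reads in the 4 libraries titled sd and 13.1 ± 23.9 CPM in tumours. The 0 allows up to 0.0572 CPM, at least 229-fold lower, and at least 20.5-fold lower without replicate 2 of the eye-antennal tumours, which held 48.9 CPM. That library also held 5050 CPM of midgut markers, against 0.504 to 12 in the other tumours. Without that library tumours averaged 13.9 CPM of CG6933, 7.04 of CG7715 and 0.654 of spok, and without replicate 1 25.2 CPM of Cpr64Ac. In the libraries titled sd the mean was 9.19 CPM for spok, 0.0743 for Cpr64Ac and 0.0237 for CG7715 without eye-antennal replicate 1, and 0.181 for CG17350 and 0.0256 for CG6933 without replicate 2. Of the genes of the transgenes, Ras85D fell (-0.65 ± 0.21, adjusted p = 0.0364), scrib rose (0.34 ± 0.09, adjusted p = 0.0151), kay and Irbp18 fell (-1.02 ± 0.24 and -0.83 ± 0.22) and Stat92E rose (0.20 ± 0.06). The genes tai (0.18 ± 0.11, adjusted p = 0.28) and hh (-0.05 ± 0.11, adjusted p = 0.785) did not pass. Without replicate 1 of the leg tumours the adjusted p was 0.129 for spok, 0.062 for ImpE2, 0.0651 for Cpr64Ac, 0.258 for CG6933 and 0.342 for CG7715. It was 0.196 for CG15818, 0.18 for Ras85D, 0.0524 for kay, 0.0799 for Irbp18 and 0.11 for Stat92E. Leaving out replicate 1 of the eye-antennal tumours gave 0.128 for spok, 0.0687 for ImpE2, 0.154 for Cpr64Ac, 0.169 for Ras85D, 0.0508 for kay, 0.0764 for Irbp18 and 0.134 for Stat92E, and leaving out replicate 2 gave 0.0606 for spok and 0.0625 for CG15818. Each of the 4 libraries titled sd, left out alone, ended the calls of Cpr64Ac, CG6933, CG7715, CG15818 and Ras85D. The call of spok also ended without replicate 2 of the leg tumours (0.117), either eye-antennal library titled sd (0.0915 and 0.0582) or leg replicate 1 (0.439). That of ImpE2 ended without replicate 1 of the eye-antennal or leg discs titled sd, and that of Irbp18 without replicate 2 of either. That of Stat92E ended without replicate 2 of either or leg replicate 1. That of scrib ended without replicate 1 of the eye-antennal tumours or replicate 2 of the eye-antennal or leg discs titled sd.

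Cell cycle genes rose in 9 of 20 cases in the libraries titled sd (14 adjusted over the list alone, median 0.40, camera adjusted p = 3.6e-06). Eye genes rose in 8 and fell in 1 of 19 cases (11 and 1 alone, median 1.01, camera adjusted p = 4.06e-05), sens by 1.56 ± 0.30. Notch targets rose in 7 of 12 (9 alone, median 0.68, camera adjusted p = 0.000114), E(spl)mgamma-HLH by 1.41 ± 0.29 and E(spl)m4-BFM by 1.22 ± 0.20. JNK targets fell in 9 of 13 cases (12 fell and 1 rose alone, median -0.84, camera adjusted p = 7.03e-05). Ets21C (-1.13 ± 0.31) and puc (-0.64 ± 0.18) had adjusted p = 0.0776 and 0.118 without replicate 1 of the leg tumours, 0.056 and 0.0894 without replicate 1 of the eye-antennal tumours, 0.0742 and 0.0738 without replicate 1 of the eye-antennal discs titled sd, and 0.0773 and 0.0598 without leg replicate 1. For puc it was 0.0623 without leg replicate 2. Camera also placed below the other genes the bZIP stress list (1 rose and 5 fell of 11; 1 and 8 alone; adjusted p = 0.0166) and the glycolysis list (5 fell of 11; 8 alone; adjusted p = 0.0152). The same held for the immune list (4 fell of 20; 6 alone; adjusted p = 0.0152), the matrix list (4 fell of 13; adjusted p = 0.0368) and the Hippo list (1 rose and 3 fell of 14; adjusted p = 0.0472). The ecdysone list (4 rose of 17; 7 rose and 1 fell alone; adjusted p = 0.0179) and the wing list (2 rose of 12; adjusted p = 0.0267) stood above the other genes, with ImpE1 at 1.17 ± 0.31 (adjusted p = 0.0502 without replicate 1 of the eye-antennal tumours). Estimating the correlation gave these lists adjusted p of 0.514 to 0.599.

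The remaining lists did not pass camera in the libraries titled sd. The JAK/STAT list had 1 higher and 4 lower of 12 (1 and 5 alone), the EGFR list 3 lower of 11 and the Wingless and Dpp list 4 higher and 2 lower of 12 (6 and 2 alone). The Hedgehog list had 3 higher and 2 lower of 9 with ci at 1.19 ± 0.10, and the leg list 5 higher and 2 lower of 15 with dac at 1.95 ± 0.26 and dysf at -4.99 ± 0.25. The polarity list had 3 higher and 4 lower of 17, heat shock and antioxidant genes 1 higher and 3 lower of 14 (1 and 4 alone) and apoptosis genes 1 higher and 2 lower of 11 (2 and 4 alone, median -0.16, mean 0.03, camera downward). Tracheal genes had 3 lower of 5 (1 higher and 3 lower alone) with serp at -1.83 ± 0.38, glial genes 1 higher and 2 lower of 7 and germline genes 2 lower of 5. Hemocyte genes had 1 lower of 10 and fat body genes 1 higher of 8 (0 alone), where replicate 2 of the eye-antennal discs held 11800 CPM of fat body markers. In the myoblast, muscle, neuronal, glue and prepupal cuticle lists no gene passed (cuticle median 0.49, mean -0.10, camera upward).

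The CG6272 knockdown (day 8) was set against eye-antennal and leg tumours to ask which tumour genes depend on this C/EBP-type factor. Ldh fell from 1470 ± 1560 to 13.7 ± 8.42 CPM (-6.68 ± 1.10, adjusted p = 0.00118). The glutathione transferase gene GstE1 fell by 3.94 ± 0.13, the EGFR ligand gene vn by 1.15 ± 0.14 and the stress gene Gadd45 by 1.91 ± 0.21. Muscle markers summed to 283 to 1680 CPM in these libraries against 248 to 343 CPM in the tumours compared, and fat body markers to 169 to 2980 against 39.5 to 283 CPM. Midgut markers stood at 892 and 5130 CPM in replicates 1 and 2 of the leg knockdown discs and at 5050 CPM in replicate 2 of the eye-antennal tumours. CG6272, Stat92E and kay libraries have a second form of file name, so a difference between sequencing runs would coincide with them. The test called 1398 genes, 523 higher and 875 lower, and 172 and 305 of these by at least 2-fold (n = 4 and 4). The count was 793 or 740 without replicate 1 of the eye-antennal or leg tumours, and 896 or 870 without replicate 1 of the eye-antennal or leg knockdown discs. It was 698 with only the libraries compared, and limma-voom gave 1220 without and 717 with the dissection as a block. The largest rises were the cuticle gene Lcp4 (12.9 ± 7.63 against 0.0724 ± 0.0837 CPM), CG7300 (15.7 ± 7.94 against 0.649 ± 0.311 CPM), the sugar transporter gene sut2 (4.45 ± 0.38), spok (22.9 ± 24.1 against 1.7 ± 2.22 CPM) and the cuticle gene Lcp1 (14.3 ± 7.34 against 0.708 ± 0.461 CPM). Beside Ldh, the largest falls were Cpr64Ac (0.0161 ± 0.0322 against 62.9 ± 82.9 CPM), the cytochrome P450 gene Cyp4p2 (1.08 ± 0.764 against 197 ± 60.1 CPM), GstD5 (0.287 ± 0.237 against 39.3 ± 27.3 CPM) and CG9521 (0.295 ± 0.307 against 46 ± 48.4 CPM). A strain difference at Cyp4p2 was not tested. The tumour means were 811 CPM for Ldh and 24.2 for CG9521 without leg replicate 1, 25.2 for Cpr64Ac without eye-antennal replicate 1, 0.654 for spok without eye-antennal replicate 2 and 0.0481 for Lcp4 without leg replicate 2. In knockdown discs spok had 12.2 and CG9521 0.187 CPM without eye-antennal replicate 1, and Cpr64Ac 0 without replicate 2. Ras85D (-1.10 ± 0.21, adjusted p = 0.00273), hh (-1 ± 0.11, adjusted p = 2.72e-05) and kay (-1.07 ± 0.24, adjusted p = 0.00938) fell, and scrib (0.26 ± 0.09), sd (0.14 ± 0.12), Stat92E (0.15 ± 0.06) and tai (0.01 ± 0.11) did not pass. Without replicate 1 of the leg tumours the adjusted p was 0.148 for spok, 0.118 for Lcp1, 0.0625 for Cpr64Ac and 0.0581 for kay, and without replicate 1 of the eye-antennal tumours 0.135, 0.109, 0.12 and 0.0543. The calls of spok and Lcp1 ended without replicate 2 of the eye-antennal (0.0655 and 0.0741) or leg tumours (0.116 and 0.0567). Of the knockdown discs, eye-antennal replicate 1 ended the calls of spok (0.0985), Lcp1 (0.0574) and Cpr64Ac (0.0588), eye-antennal replicate 2 those of spok (0.0588) and Cpr64Ac (0.0509), leg replicate 1 that of Lcp1 (0.0654) and leg replicate 2 that of spok (0.481).

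EGFR outputs fell in 8 of 11 cases under CG6272 knockdown (9 adjusted over the list alone, median -0.62, camera adjusted p = 1.31e-06), ImpL2 by 2.59 ± 0.34 and sty by 0.89 ± 0.17. Hippo targets fell in 7 of 14 (10 alone, median -0.34, camera adjusted p = 2.36e-05), dally by 0.59 ± 0.11. Glycolytic genes fell in 9 of 11 cases (median -1.14, camera adjusted p = 0.000177). Ald1 was at -1.71 ± 0.40 (adjusted p = 0.0702 and 0.0694 without replicate 1 of the leg or eye-antennal tumours). The bZIP stress genes fell in 7 of 11 (8 alone, median -0.77, camera adjusted p = 0.000177), with Xrp1 at -0.77 ± 0.14. Apoptosis genes fell in 5 of 11 cases (7 fell and 1 rose alone, median -0.37, camera adjusted p = 0.000638), Corp by 2.40 ± 0.25 and Dronc by 0.92 ± 0.10. Heat shock and antioxidant genes fell in 6 of 14 (6 fell and 1 rose alone, median -0.70, camera adjusted p = 0.00445), GstD1 by 1.36 ± 0.23. JNK targets fell in 7 of 13 (8 alone, median -0.57, camera adjusted p = 0.00911), Ilp8 by 2.96 ± 0.56. JAK/STAT genes fell in 5 of 12 cases (median -0.50, camera adjusted p = 0.0441), upd1 by 1.73 ± 0.27 and upd3 by 1.55 ± 0.29, and the leg list had 1 higher and 4 lower of 15 (camera adjusted p = 0.02). With an estimated correlation the adjusted p of these lists was 0.0618 for apoptosis and 0.275 to 0.495 for the others.

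Larval muscle genes rose in 6 of 8 cases under CG6272 knockdown (8 adjusted over the list alone, median 2.53, camera adjusted p = 0.000177). Among them were Mlc1 at 3.62 ± 0.88 (2.58 ± 0.85, adjusted p = 0.0757 without replicate 1 of the leg knockdown discs, and 0.0749 or 0.0788 without replicate 1 of the eye-antennal or leg tumours) and bt at 2.64 ± 0.55. Myoblast genes rose in 3 of 6 (camera adjusted p = 0.00279) and hemocyte genes in 2 of 10 (camera adjusted p = 0.0441). Cell cycle genes rose in 6 of 20 cases (8 alone, median 0.30, camera adjusted p = 0.000717). Mcm5 was at 0.62 ± 0.14. Eye genes rose in 2 of 19 (1 alone, camera adjusted p = 0.00824) and matrix genes in 1 of 13 (camera adjusted p = 0.0497). No fat body gene passed over all genes, though 5 of 8 rose adjusted over the list alone (camera adjusted p = 0.00911). These lists had adjusted p of 0.384 to 0.529 with an estimated correlation. Outside camera's calls, the Hedgehog list had 2 higher and 3 lower of 9 (3 and 3 alone). Among them were ci at 1.09 ± 0.10 and en at -0.79 ± 0.18. The Wingless and Dpp list had 1 higher and 3 lower of 12, polarity genes 3 higher and 4 lower of 17 (4 and 4 alone) and Notch targets 1 higher and 1 lower of 12. Glial genes had 2 and 2 of 7 (3 and 2 alone), and the wing (median -0.04, mean 0.14, camera upward) and neuronal lists 1 higher each (neuronal 1 and 1 alone). In the ecdysone, immune, tracheal, glue, prepupal cuticle (median -0.60, mean -0.47, camera upward) and germline lists no gene passed (1 germline gene fell alone).

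The libraries titled tai, a coactivator of the ecdysone receptor and of Yorkie, gave fewer calls than those of sd, CG6272 or Stat92E. They had 267 called genes, 96 higher and 171 lower, and 41 and 53 of these by at least 2-fold (n = 3 and 4), with 1620 genes at an unadjusted p under 0.05. The count was 130, 119 or 153 without replicate 1 of the eye-antennal tumours, replicate 1 of the leg tumours or replicate 2 of the eye-antennal discs titled tai. It was 16 with only the libraries compared and 633 with DESeq2, and limma-voom gave 237 without and 84 with the dissection as a block. The stress gene Gadd45 (-1.14 ± 0.24), the apoptosis gene Corp (-1.18 ± 0.28) and the insulin antagonist gene ImpL2 (-1.70 ± 0.39) fell, and the Notch target E(spl)m2-BFM (0.93 ± 0.21) rose. Their adjusted p was 0.0755, 0.133, 0.0969 and 0.107 without replicate 1 of the leg tumours, 0.0545, 0.116, 0.0937 and 0.118 without replicate 1 of the eye-antennal tumours, and 0.0668, 0.0824, 0.0848 and 0.114 without replicate 2 of the eye-antennal discs titled tai. Replicate 1 of these discs ended the calls of Corp (0.0789) and ImpL2 (0.0609), and replicate 2 of the leg tumours that of E(spl)m2-BFM (0.0524). The largest rises were the cuticle genes Lcp4 (68.2 ± 98.4 against 0.0724 ± 0.0837 CPM) and Lcp2 (29.6 ± 49.4 against 0.0766 ± 0.103 CPM). They were joined by CG13403 (10.3 ± 10.3 against 0.315 ± 0.094 CPM), CG17738 (39.4 ± 62.7 against 1.21 ± 1.5 CPM) and CG15905 (3.26 ± 0.39). Without replicate 1 of the eye-antennal discs titled tai the log2 change was 5.23 ± 0.96 for Lcp4, the means 11.8 CPM for Lcp4, 1.12 for Lcp2, 4.88 for CG13403, 3.22 for CG17738 and 1.07 for CG17350, and the adjusted p 0.226 for Lcp2, 0.187 for CG13403 and 0.21 for CG17738. CG33509 had 0 CPM without replicate 2 of these discs, and in tumours Lcp4 had 0.0481 and Lcp2 0.0294 without leg replicate 2 and CG17738 0.46 without eye-antennal replicate 2. Lcp4 had adjusted p = 0.0594 and 0.0651 without replicate 1 of the eye-antennal or leg tumours, Lcp2 0.105 and 0.125, CG13403 0.135 and 0.139, and CG17738 0.123 and 0.155. Leaving out replicate 2 of the eye-antennal or leg tumours gave 0.0798 and 0.067 for Lcp2 and 0.0968 and 0.0845 for CG13403, and 0.0868 for CG17738 in the leg case. The largest falls were CG33509 (0.0502 ± 0.0869 against 17.8 ± 5.27 CPM) and the sodium channel gene ppk13 (0.125 ± 0.0462 against 33.6 ± 6.61 CPM). Others were the pigmentation gene y (6.34 ± 1.67 against 693 ± 222 CPM), CG17350 (2.53 ± 2.66 against 84.6 ± 18.7 CPM) and dysf, a factor of leg joints and trachea (5.73 ± 3.13 against 267 ± 93.2 CPM). A strain difference at genes with near-absent reads in 1 genotype, such as CG33509 and ppk13 here, was not tested. Of the genes of the transgenes, hh fell (-0.72 ± 0.13, adjusted p = 0.00677). The genes Ras85D (-0.66 ± 0.24), scrib (0.28 ± 0.10), Irbp18 (-0.77 ± 0.25), kay (-0.44 ± 0.27), Stat92E (0.17 ± 0.07) and sd (0.05 ± 0.13) did not pass, with adjusted p of 0.122 to 0.907.

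Camera placed above the other genes in the libraries titled tai the Notch targets (3 rose of 12; 8 adjusted over the list alone; adjusted p = 4.29e-05) and the eye genes (1 rose of 19; 3 alone; adjusted p = 8.28e-05). It did so for cell cycle genes (0 of 20; adjusted p = 0.000969), muscle genes (0 of 8, 6 alone; adjusted p = 0.00156), myoblast genes (1 of 6; adjusted p = 0.00594) and wing genes (1 of 12; adjusted p = 0.0149). Below the other genes were the EGFR outputs (1 rose and 3 fell of 11; 1 and 7 alone; adjusted p = 0.000798) with pnt at -0.61 ± 0.14 (adjusted p = 0.0979, 0.0937 and 0.0832 without replicate 1 of the leg tumours, replicate 1 of the eye-antennal tumours or replicate 2 of the eye-antennal discs titled tai). So were the glycolysis list (0 of 11; 8 fell alone; adjusted p = 0.000798), the bZIP list (2 fell of 11; 6 alone; adjusted p = 0.00126) and the Hippo list (0 of 14; 2 fell alone; adjusted p = 0.0271). With an estimated correlation the adjusted p of these lists was 0.431 to 0.505. The JNK and apoptosis lists each had 2 lower genes (apoptosis 3 alone), and the Hedgehog list had 1 higher (ci, 1.03 ± 0.11) and 1 lower. The leg list had 1 higher and 1 lower (2 and 2 alone), and the Wingless and Dpp (2 alone), polarity (2 alone), hemocyte and glial (3 higher and 1 lower alone) lists 1 higher each. In the JAK/STAT, matrix, ecdysone, heat shock, immune, fat body, tracheal, neuronal, glue, prepupal cuticle and germline lists no gene passed. Alone, 1 JAK/STAT and 1 germline gene fell and 1 heat shock or antioxidant gene rose and 3 fell. Summed muscle markers stood at 3040 CPM in replicate 1 of the eye-antennal discs.

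The Stat92E knockdown (day 8) was set against eye-antennal and leg tumours to ask which genes depend on the JAK/STAT pathway's transcription factor. Of 12 JAK/STAT genes 3 fell, Stat92E itself among them, against 4 in the libraries titled sd and 5 under CG6272 knockdown. The STAT target Socs36E fell by 1.31 ± 0.15 and the receptor gene dome by 0.39 ± 0.09. Of 19 eye genes 13 rose, among them gl, a zinc finger factor of photoreceptors (4.17 ± 0.54, adjusted p = 0.000298), toy (3.20 ± 0.65), ey (2.54 ± 0.54), sens (2.29 ± 0.32), Optix (2.12 ± 0.42) and eya (1.71 ± 0.28). These log2 changes are means over both discs, and low levels in leg tumours enlarge them. In eye-antennal discs, with 1 knockdown library, gl stood at 140 against 46.3 CPM, toy at 211 against 56.7 and ey at 71.5 against 25.1 CPM, and in leg discs at 9.5 against 0.0805, 12.9 against 0.54 and 4.36 against 0.358 CPM. Of the 13 genes 9 were under 5 CPM in leg tumours. All 13 were higher by mean in eye-antennal discs, and eye-antennal tissue in the leg dissections was not tested. The test called 1303 genes, 638 higher and 665 lower, and 153 and 190 of these by at least 2-fold (n = 3 and 4), and 756 or 840 without replicate 1 of the eye-antennal or leg tumours. It called 227 with only the libraries compared, and limma-voom gave 1202 without and 757 with the dissection as a block. Beside gl, the largest rises were CG5653 (13.3 ± 17.6 against 5.67 ± 7.79 CPM; 3.17 against 0 in leg discs), side-II (18.8 ± 11 against 3.82 ± 4.27 CPM; 13.2 against 0.213 in leg discs), CG34377 (82.9 ± 118 against 47.8 ± 62.4 CPM; 14.8 against 0.161 in leg discs) and CG15905 (53.8 ± 23.1 against 3.88 ± 1.73 CPM). The largest falls were Cyp4p2 (0.165 ± 0.162 against 197 ± 60.1 CPM), CG7714 (0.0469 ± 0.0813 against 36.7 ± 41.5 CPM), CG17350 (0.832 ± 0.809 against 84.6 ± 18.7 CPM), y (8.06 ± 2.92 against 693 ± 222 CPM) and CG9521 (0.799 ± 0.832 against 46 ± 48.4 CPM). A strain difference at Cyp4p2 and y was not tested. Without replicate 2 of the eye-antennal tumours the tumour means were 17 CPM for CG7714, 8.62 for gl, 2.06 for CG5653, 2.23 for side-II and 20 for CG34377, and without leg replicate 1 24.2 for CG9521. In knockdown discs Cyp4p2 had 0.071, CG9521 0.319 and CG7714 0 CPM without leg replicate 2, and CG17350 0.387 without the eye-antennal library. Ras85D (-0.90 ± 0.24, adjusted p = 0.0232), Irbp18 (-1.08 ± 0.25, adjusted p = 0.0114) and kay (-0.91 ± 0.28, adjusted p = 0.0449) fell, and scrib (0.22 ± 0.10), hh (-0.30 ± 0.12), sd (0.25 ± 0.13) and tai (0.18 ± 0.12) did not pass. Without replicate 1 of the eye-antennal tumours the calls of CG7714, CG9521, Ras85D and kay ended. Those of CG7714, Ras85D and kay ended without replicate 1 of the leg tumours or leg knockdown discs. Leg replicate 2 of the knockdown ended those of CG7714 and Ras85D, and eye-antennal tumour replicate 2 that of CG7714.

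Eye genes rose in 13 of 19 cases under Stat92E knockdown (16 adjusted over the list alone, median 1.58, camera adjusted p = 1.8e-10). Cell cycle genes rose in 7 of 20 (9 alone, median 0.37, camera adjusted p = 1.36e-05). CycB3 was at 0.48 ± 0.08. Notch targets rose in 5 of 12 (6 alone, median 0.55, camera adjusted p = 3.88e-05), with E(spl)m2-BFM at 1.14 ± 0.21 and E(spl)m7-HLH at 0.95 ± 0.14. Wingless and Dpp genes rose in 4 and fell in 1 of 12 cases (6 and 2 alone, camera adjusted p = 0.0104), Wnt6 by 1.57 ± 0.17, and wing genes rose in 2 of 12 (3 alone, camera adjusted p = 0.0251). JNK targets fell in 6 of 13 cases (10 fell and 1 rose alone, median -0.69, camera adjusted p = 0.00059). Ets21C was at -1.54 ± 0.36. JAK/STAT genes fell in 3 of 12 (5 fell and 1 rose alone, median -0.75, camera adjusted p = 0.00795). That list holds Stat92E, the hairpin's own target. The bZIP list (3 fell of 11; 6 alone; adjusted p = 0.0198), the Hippo list (2 fell of 14; adjusted p = 0.025) and the glycolysis list (0 of 11; adjusted p = 0.0432) also stood below the other genes. With an estimated correlation the adjusted p was 0.272 for the eye genes and 0.438 to 0.784 for the other lists.

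Outside camera's calls, the Hedgehog list had 3 higher (ci, 1.31 ± 0.11) and 2 lower of 9 (en, -1.22 ± 0.21; 3 and 3 alone) under Stat92E knockdown. Leg genes had 2 higher (dac, 2.01 ± 0.28) and 1 lower of 15 (dysf, -4.67 ± 0.31; 3 and 1 alone; list median 0.20, mean -0.06, camera upward). Heat shock and antioxidant genes had 1 higher and 3 lower of 14 (1 and 4 alone), EGFR outputs 1 higher and 2 lower of 11 and matrix genes 3 lower of 13. Apoptosis genes had 3 lower of 11 (2 higher and 3 lower alone, median -0.08, mean 0.07, camera downward) and immune genes 2 lower of 20 (0 alone). Polarity genes had 2 higher of 17 (3 higher and 1 lower alone, median -0.01, mean 0.01, camera upward), ecdysone genes 2 higher of 17, and myoblast and glial genes 1 higher each (glial 3 higher and 2 lower alone). In the hemocyte, fat body (median -0.09, mean 0.24, camera upward), muscle, tracheal, neuronal, glue, prepupal cuticle and germline (median -0.29, mean 0.28, camera downward) lists no gene passed. Alone, 2 tracheal genes fell and 1 cuticle gene rose.

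The single library titled kay was set against the eye-antennal tumours, with a spread borrowed from the other groups and no replicate check of its own. It gave 18 genes, 7 higher and 11 lower, and 1331 at an unadjusted p under 0.05. The count was 9 or 5 without replicate 1 or 2 of the eye-antennal tumours. The higher genes included Osi14 (35.6 against 4.35 ± 0.751 CPM), the serpin gene Spn47C (2.03 ± 0.26), the synaptotagmin gene Syt4 (1.45 ± 0.24), plx (1.18 ± 0.22) and ci (0.96 ± 0.17). The lower genes included CG17350 (0.776 against 97.8 ± 6.5 CPM), Cyp4p2 (2.26 against 231 ± 6.12 CPM), dysf (4.66 against 336 ± 8.94 CPM), y (14.5 against 878 ± 82.1 CPM) and Cyp4p1 (2.2 against 82 ± 4.93 CPM). A strain difference at Cyp4p2 and y was not tested. Without replicate 1 of the tumours the adjusted p was 0.172 for Osi14, 0.138 for Syt4, 0.253 for plx and 0.174 for ci, and without replicate 2 it was 0.129, 0.102, 0.0633 and 0.0891 for these and 0.0537 for Spn47C. Of the list genes only ci and dysf passed over all genes. Adjusted over the list alone, 10 of 19 eye genes, 6 of 12 Notch targets and 4 of 9 Hedgehog genes rose. So did 3 of 12 Wingless and Dpp, 3 of 17 polarity, 1 of 12 wing and 2 of 15 leg genes, and 2 leg, 2 apoptosis and 1 heat shock or antioxidant gene fell. Camera placed the eye (adjusted p = 5.39e-08), Notch (2.46e-05), cell cycle (0.002), polarity (0.002), wing (0.00374), neuronal (0.0263), Hedgehog (0.0263) and Wingless and Dpp (0.0302) lists above the other genes, with adjusted p of 0.414 to 0.662 with an estimated correlation. Median and mean differ in sign in the matrix (0.10 and -0.01) and tracheal lists (-0.11 and 0.17). Camera is upward against a median below 0 in the JAK/STAT (-0.03), Hippo (-0.01), fat body (-0.20), tracheal and cuticle lists (-0.64) and against a mean below 0 in the leg list (-0.11). Ras85D (-1.03 ± 0.37, adjusted p = 0.258), scrib (0.54 ± 0.15, adjusted p = 0.166), hh (-0.41 ± 0.19), Irbp18 (-0.87 ± 0.39), Stat92E (0.25 ± 0.11), sd (0.33 ± 0.20) and tai (0.33 ± 0.19) did not pass.

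**Figure D2:**
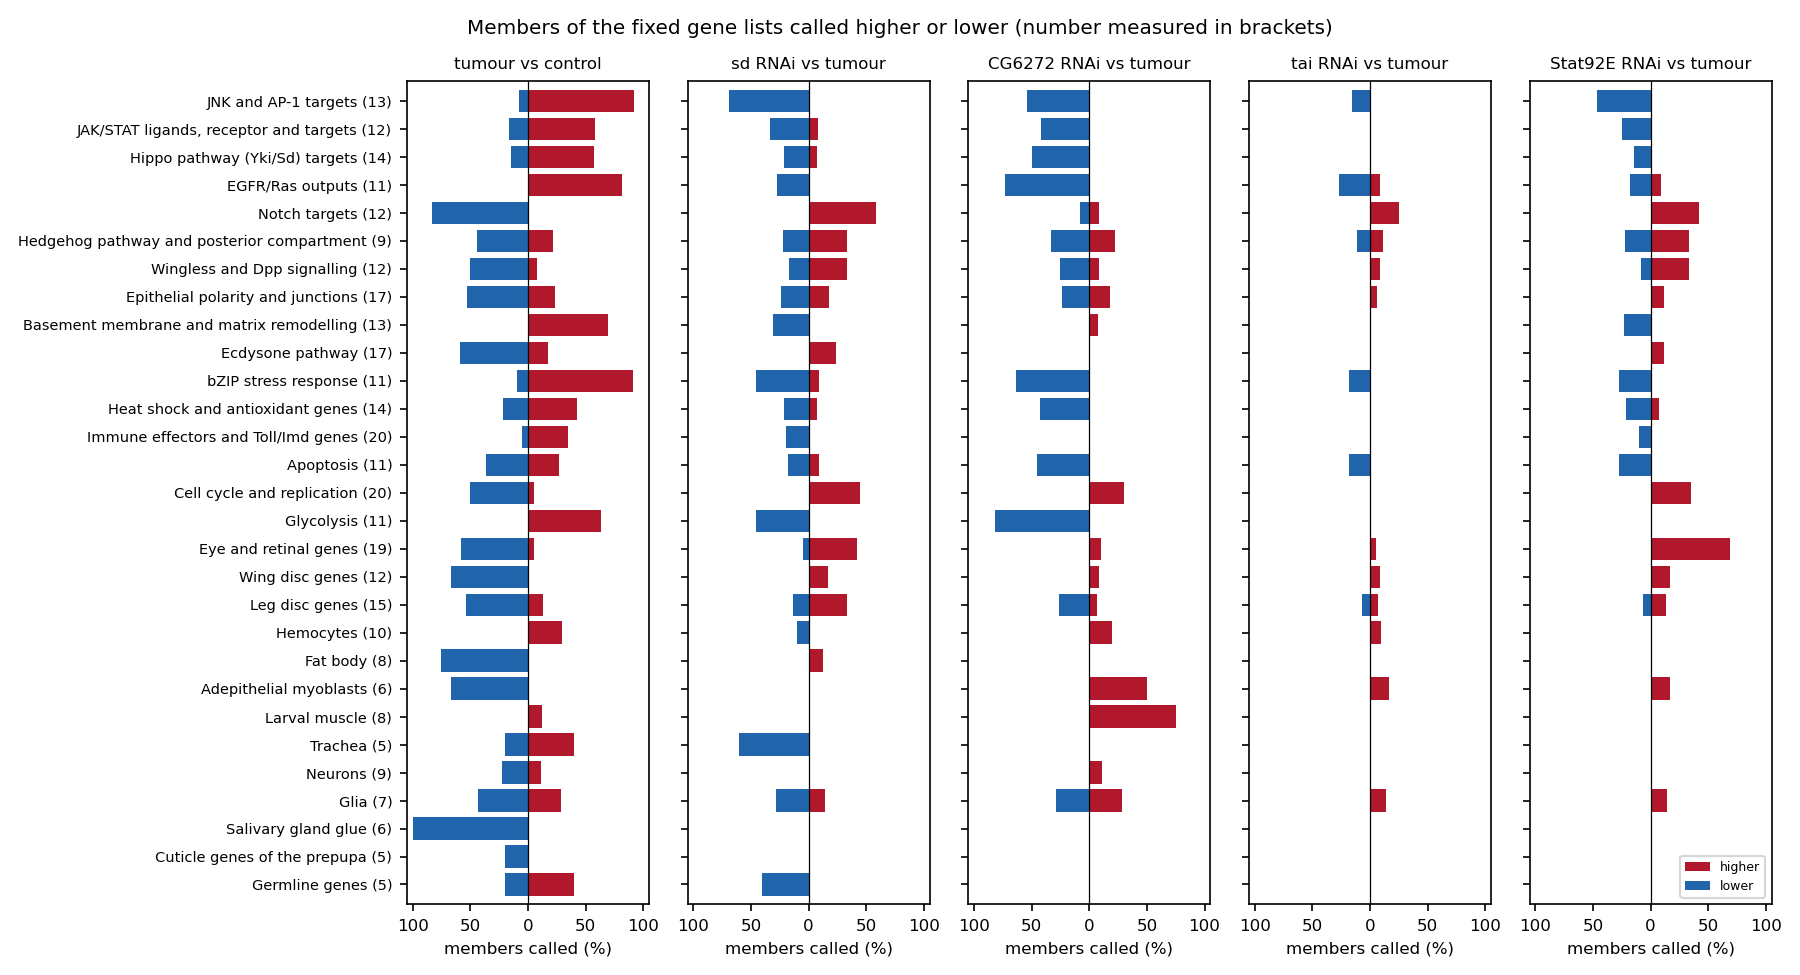
Share of each fixed gene list's measured members called higher (right, red) or lower (left, blue), in percent, for the tumour against control discs and for 4 hairpin genotypes against tumour discs. JNK targets rise in the tumour (12 of 13) and fall in the libraries titled sd (9 of 13), and eye genes fall in the tumour (11 of 19) and rise under Stat92E knockdown (13 of 19).

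Whether the hairpins reverse the tumour's programme was asked with genes called in wing discs, which share no library with these comparisons, though the wing tumours have the same days and replicate numbers as the tumours compared. Controls were of day 5, tumours of days 9 and 11, and sd, CG6272 and Stat92E libraries of days 7 to 8. Reversal there could not be separated from age. In the libraries titled sd the 956 genes raised at least 2-fold in tumour wing discs had a median log2 change of -0.67, and 395 of them fell past the threshold against 19 that rose. Under CG6272 knockdown the median was -0.48 (336 fell, 38 rose), under Stat92E knockdown -0.59 (240 fell, 25 rose), in the libraries titled tai -0.33 (76 fell, 7 rose) and in the library titled kay -0.29 (3 fell, 2 rose). The 266 genes lowered in tumour wing discs had medians of 0.46 (95 rose, 4 fell), 0.13 (41 rose, 14 fell), 0.41 (79 rose, 1 fell), 0.37 (26 rose, 2 fell) and 0.24 (1 rose, 0 fell) in the same order. Over all genes called in wing discs, with no 2-fold minimum, the medians in that order were -0.411, -0.299, -0.384, -0.229 and -0.245 for the raised and 0.197, 0.073, 0.176, 0.097 and 0.087 for the lowered genes. With wing genes taken from tumour replicate 1 and the hairpin genotypes set against tumour replicate 2 they were -0.396, -0.213, -0.331, -0.114 and -0.147 for the raised and 0.46, 0.181, 0.396, 0.333 and 0.239 for the lowered genes. The other way round they were -0.693, -0.539, -0.584, -0.352 and -0.242, and 0.297, -0.029, 0.266, 0.288 and 0.082, where the lowered genes did not pass under CG6272 knockdown (camera adjusted p = 0.609). Without replicate 1 of the leg tumours the median of the lowered genes under CG6272 knockdown was 0.212 and that of the raised genes in the libraries titled tai -0.215. The median of the raised genes in the library titled kay was -0.102 without replicate 1 of the eye-antennal tumours. Camera's adjusted p was 2.43e-21 to 0.00168 for the raised and 1.72e-19 to 0.000689 for the lowered genes. With an estimated correlation none of these calls held: the adjusted p was 0.0667, 0.0967, 0.0967, 0.139 and 0.431 for the raised genes and 0.0559, 0.295, 0.0559, 0.0559 and 0.168 for the lowered genes.

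**Figure D3:**
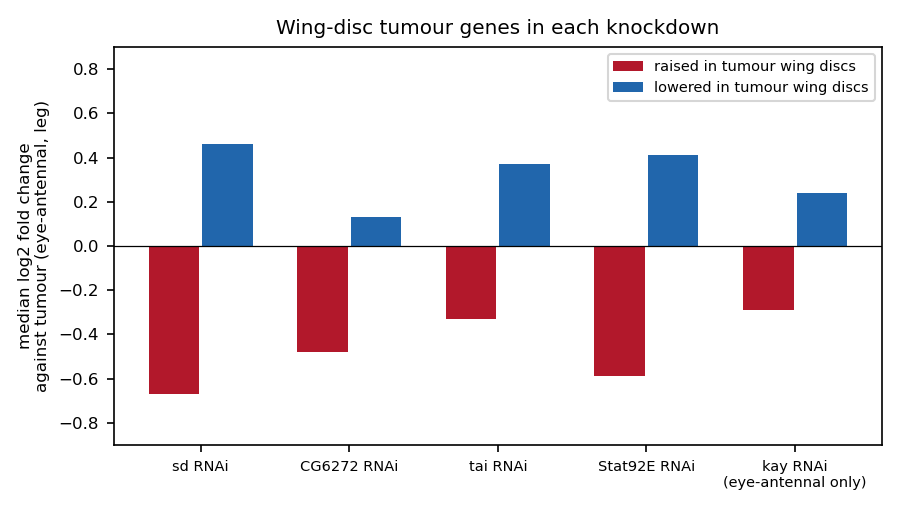
Median log2 fold change of the 956 genes raised (red) and the 266 genes lowered (blue) at least 2-fold in tumour wing discs, measured in each hairpin genotype against tumours of eye-antennal and leg discs (kay in eye-antennal discs). All 5 red bars lie below 0 and all 5 blue bars above 0.

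The genes changed alike in the 4 hairpin genotypes with more than 1 library, of which those titled sd and tai did not lower their target past the threshold, were counted to ask what they share. Of them 44 rose and 76 fell in all 4, where independent calls at the same rates would give 0.0308 and 0.124. The higher set held the patterning genes ci, dac and bi, the Wingless receptor genes fz and arr, the glial factor gene repo and the receptor gene sev. The lower set held dysf, the insulin antagonist gene ImpL2, the stress genes Xrp1 and Corp, and the nitric oxide synthase gene Nos. Members of these sets outside the fixed lists are named after their values were seen. In the libraries titled tai the calls of dac, sev, Xrp1, Corp and ImpL2 ended without replicate 1 of the eye-antennal or leg tumours. They also ended without replicate 2 of the eye-antennal discs titled tai. Those of sev, Corp and ImpL2 ended without replicate 1 of these discs, and that of Xrp1 without replicate 2 of the eye-antennal tumours. In the libraries titled sd the call of Xrp1 ended without replicate 1 of the leg tumours or of the eye-antennal or leg discs. Pairs of these genotypes shared the most between sd and Stat92E, with 439 genes higher in both and 469 lower in both. The higher and lower sets had 22 and 27 genes without replicate 1 of the eye-antennal tumours, 21 and 25 without replicate 1 of the leg tumours, and 21 and 30 without replicate 2 of the eye-antennal discs titled tai. The lower set had 144 without replicate 2 of the leg tumours, and 49 or 46 without replicate 1 of the eye-antennal or leg discs titled sd. Between sd and Stat92E the genes higher and lower in both were 227 and 255 without replicate 1 of the eye-antennal tumours and 284 and 235 without replicate 1 of the leg tumours. Those lower in both were 311 without leg replicate 1 titled sd and 301 without leg replicate 1 of the Stat92E knockdown. The 4 comparisons use the same tumour libraries.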

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

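The tests of mitochondrial genes, control leg replicate 2, shared tumour libraries and driver cell share were chosen only after the result was seen. So was the day of the tai libraries. Of 72 tests of 1 measure in 1 genotype, 7 found a library apart. Discs were pooled, so what chance gives is unknown.

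In control leg replicate 2, genes of the tumour were detected: Ilp8 stood at 14.2 CPM (0 to 0.295 in the other control libraries), Ldh at 55.8 CPM (17.7 to 29.3), and reads aligned to several places at 0.314 for each gene read (0.198 to 0.216). If RNA or reads of a tumour sample had entered this library, tumour genes would stand at a common share of their tumour level. Of 4 such genes 75% lay within 2-fold of the median share (1.32% to 19%), which keeps both this and a stress response open. In a wider set of 23 genes, added after the first was undecided, the median share was 2.53%, against at most 0.395% in the other control libraries, but only 52.2% lay within 2-fold of it, so that tumour RNA in this library and a stress response in these larvae both stay open.

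The low level of 4 mitochondrial genes outside the control libraries may reflect a strain variant of the mitochondrial genome: the lowest control level of mt:CoIII, 158 CPM, was 94.2 times the highest in any other library, 1.68 CPM. A loss of all mitochondrial RNA in the tumour genotype stays open, since the other mitochondrial features kept 56.6% of their control level but held only 6.59 CPM in controls. No sequence was read here.

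In 4 hairpin genotypes 120 genes moved alike (44 higher and 76 lower). Both sets shrank without some single libraries, as given above. In 20 simulations with shared tumour libraries the number was 0. They held no dissection effect, so they cannot tell how many of the 120 come from shared tumour libraries. With separate tumour dissections the covariance between pairs was 0.0699 (CG6272 and tai) to 0.247 (sd and Stat92E). It was 0.19 and 0.404 for these pairs with the same tumour libraries. Younger larvae as the cause in all 4 are argued against, since the tai libraries are of day 10, a mean of 0 days from tumours (days 9 and 11). For sd (days 7 to 8), CG6272 and Stat92E (day 8) younger larvae stay open: the day 11 minus day 9 difference in tumours had a median of -0.20 against the direction needed (-0.25 to -0.11 in the discs), but each day is 1 dissection, so that day cannot be parted from dissection and the discs are no independent samples. A smaller share of driver cells in the hairpin libraries stays open: Ras85D fell and scrib rose past the threshold in 1 of 5 hairpin genotypes, that titled sd. There the calls of Ras85D and scrib ended when single libraries were left out, as given above. Ras85D and hh, expressed in driver cells, were lower in 5 of 5 (hh -1 to -0.05), hh past the threshold under CG6272 knockdown and in tai (adjusted p = 2.72e-05 and 0.00677) and not in sd (0.785). The anterior gene ci, 1 of the 44, was higher in 5 of 5. Its log2 changes were 1.19 in sd, 1.09 in CG6272, 1.03 in tai, 1.31 in Stat92E and 0.96 in kay. The 5 comparisons share the tumour libraries, so their common signs are no separate evidence. A common effect of the hairpins on the tumour stays open. A shared strain background, for example at y, was not tested.

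Glue markers stood at 1780 CPM in control eye-antennal replicate 1 (2 to 74.1 in the other controls) and at 23.3 CPM in tumour wing replicate 2 (0.794 to 1.97). Midgut markers stood at 5050 CPM in tumour eye-antennal replicate 2 (0.504 to 12 in the other tumours), and at 5130 and 892 CPM in CG6272 leg replicates 2 and 1, and fat body markers at 11800 CPM in replicate 2 of the eye-antennal discs titled sd (36.1 to 257). The tumour effect depended on the disc in 322 genes. Reads aligned to several places averaged 2.36 for each gene read in tumours and 0.227 in controls, and the day 11 to day 9 ratio in tumours was 0.696, 0.555 and 0.482 in eye-antennal, leg and wing discs.

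With single libraries as units, chance can be excluded for the tumour comparison: 1 of 100 splits, the real one, called as many genes (4723), and the highest other, 1804, exchanged control eye-antennal replicate 2 and tumour wing replicate 2. The other splits drawn that exchanged 1 pair called 0 genes, and why this one differed was not tested. In 34 splits each for sd (1058 genes, highest other 2), CG6272 (771, highest other 0), tai (54, highest other 2) and Stat92E (408, highest other 1), 1 split, the real one, called as many. These splits could exclude chance only if the libraries of 1 genotype were independent. Deviations of discs with the same number correlated (median 0.26), so chance is not excluded by them. With whole dissections as units the splits are too few.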

How the results depend on the processing

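Tests chosen only after the result was seen are limma-voom without a block, the fit without the 5 libraries with most reads of other tissues, the sd-titled eye-antennal discs alone, and the reversal with separate tumour dissections. The cause of the moves below was not tested.

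With the dissection as a random block in limma-voom, the counts were 781 for disc dependence, 2114 and 1408 for differences among control and tumour discs, 1132 for sd, 717 for CG6272, 84 for tai, 757 for Stat92E and 38 for kay. Without a block, limma-voom gave 174 for disc dependence and 46 for kay. DESeq2 gave 882 for disc dependence, 633 for tai and 255 for kay. With only the libraries compared the counts were 2135 for leg, 1274 for wing, 127 for disc dependence, 103 for differences among tumour discs, 1263 for sd, 698 for CG6272, 16 for tai, 227 for Stat92E and 2 for kay. Without the 5 libraries with most reads of other tissues they were 990 for eye-antennal discs, 53 for disc dependence, 601 and 318 for differences among control and tumour discs, 947 for sd, 658 for CG6272, 83 for tai, 752 for Stat92E and 6 for kay. The eye-antennal discs titled sd alone gave 275 genes, and read as kay 323.

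With an estimated correlation no reversal call held: the medians of raised genes were -0.672, -0.478, -0.331, -0.586 and -0.294 and of lowered genes 0.457, 0.13, 0.372, 0.411 and 0.243 for sd, CG6272, tai, Stat92E and kay. With separate tumour dissections only the lowered genes under CG6272 knockdown turned, with wing genes from dissection 2 (-0.029).

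Against other hairpins with the same form of file name (8 libraries), CG6272 gave 807, Stat92E 276 and kay 4 genes. The sign turned in CG6272 for Cyp4p2 (1.67), ci (-0.18), y (2.25), CG17350 (1.48), en (0.19) and the lowered genes (-0.315), in Stat92E for CG9521 (0.26), Ras85D (0.17), kay (0.25), Irbp18 (1.12) and dysf (1.43), and in kay for ci (-0.19), Cyp4p2 (3.36), dysf (0.38), Cyp4p1 (0.27) and the raised genes (0.297). The raised genes had -0.053 in CG6272 and -0.103 in Stat92E, and the lowered genes 0.064 in kay, without a call.

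Leaving out each library in turn, where a group then has 1 sample that is assumed to vary like the other groups, gave 1787 to 2039 genes for eye-antennal and 1786 to 2807 for wing discs, 171 to 447 for disc dependence, 684 to 1190 and 472 to 801 for differences among control and tumour discs, 1254 to 2267 for sd, 740 to 1671 for CG6272, 119 to 376 for tai, 756 to 1466 for Stat92E and 5 to 9 for kay. The raised genes in kay had -0.366 to -0.102. The lowest hairpin counts came without replicate 1 of the eye-antennal (sd, Stat92E) or leg tumours (CG6272, tai). That of kay came without eye-antennal tumour replicate 2. The log2 change of sd in the libraries titled sd turned to 0.05 without leg replicate 1, and its lowest value was -0.26.

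Numbers do not pair across genotypes: deviations of same-numbered libraries correlated with a median of -0.02 in 58 pairs of 2 genotypes, and 0.26 in 8 pairs of 1 genotype. Blocking on the dissection in limma-voom ended 78 calls of 299 named gene results, and limma-voom without a block 48. With the replicate block kay gave 11 genes, and no other count moved past 1.5 times. Of 299 named gene results 150 kept their side of the threshold in every alternative other than leaving out 1 library, and 223 leaving out each library. Calls of named genes ended in 64 of 287 without replicate 1 of the eye-antennal tumours and in 56 of 273 without replicate 1 of the leg tumours. They ended in 16 of 42 without replicate 1 of the eye-antennal or of the leg discs titled sd, and in 12 and 13 of 42 without replicate 2. For tai 10 and 14 of 27 ended without replicates 1 and 2 of the eye-antennal discs, for CG6272 4 to 7 of 41 and for Stat92E 4 of 32 without 1 knockdown library.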

Other observations

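The values in this part were picked after they were seen, and none was tested further.

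Single genes differed by genotype, with low levels in some genotypes. A difference in strain background was not tested, and no sequence was read. The body colour gene y averaged 264, 547 and 483 CPM in control and 878, 508 and 531 CPM in tumour eye-antennal, leg and wing discs, and 5.65 to 49.5 CPM in the groups of all 5 hairpin genotypes. The cytochrome P450 gene Cyp4p2 stood at 0.07 to 2.26 CPM in CG6272, Stat92E and kay groups and at 85.9 to 231 CPM in the other groups, and CG33509 and ppk13 were near 0 in the tai groups alone among all groups. CG6272, Stat92E and kay libraries have the second form of file name, so a sequencing run may differ. Against other hairpin libraries of that form the log2 change under CG6272 knockdown was 1.67 for Cyp4p2 and 2.25 for y. The tracheal and leg gene dysf stood at 335, 198 and 226 CPM in eye-antennal, leg and wing tumours, against 6.72, 53.1 and 21.1 CPM in controls. It stood at 2.2 to 17.6 CPM in the groups of the hairpin genotypes.

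Genes raised in tumours differed between dissections of the same genotype. Ras85D stood at 1001, 1133 and 1305 CPM in replicate 1 of eye-antennal, leg and wing tumours (day 9) and at 657, 680 and 585 CPM in replicate 2 (day 11). Irbp18 stood at 82, 81.5 and 110 CPM against 51.6, 46.5 and 51.5 CPM, and kay at 433, 586 and 544 CPM against 242, 301 and 292 CPM.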
